A study of Mus musculus with 21 samples.

How the data were processed

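Gene expression was measured by RNA sequencing of liver from 21 mice, 1 library per mouse. Per the labels, all mice were C57BL/6 animals of the genotype IGF-II/LDLR-/-, ApoB 100/100, a name that refers to insulin-like growth factor II, to the loss of the LDL receptor and to mice that make only the long form of apolipoprotein B. Per the labels, chow animals received chow with placebo or rosuvastatin, an inhibitor of HMG-CoA reductase, for 12 weeks from the age of 4 months. Western-diet animals received Western diet for 2 months and then Western diet with placebo or rosuvastatin for 12 weeks, and their age is not given. The groups were Western diet with placebo (n = 4), Western diet with rosuvastatin (n = 6), chow with placebo (n = 5) and chow with rosuvastatin (n = 6). Per the labels, total RNA was depleted of ribosomal RNA, hydrolysed with base, tailed with poly(A), reverse transcribed, circularised and amplified. The labels give the same protocol for every library and name no batch, sex or time of collection.

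The authors supplied 1 table with a value per gene and library. It holds 22796 genes, each with 1 RefSeq transcript and its coordinates on genome build mm9. The labels name TopHat and HOMER, with no version and no statement of what each did. The column headers give no unit for the deposited library values, which were read as RPKM (reads scaled to transcript length and to the library's total) from the values themselves. In every library the deposited values of genes with up to 200 reads fell on steps of 1 whole read within a tolerance of 0.1 read, which also gives the depth. The same table has, per the file headers, the authors' log fold change of rosuvastatin against placebo on each diet, whose base was read as log2 from the group means, and the authors' FDR (a p-value adjusted for the genes tested). The authors' test is not stated. These columns were used only for a comparison with the values computed here. Which reads were counted, and how reads shared between similar genes were treated, is not stated.

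The depth, the read total behind the RPKM values as recovered from those steps, ranged from 2117586 to 14188533 reads per library. The range was 2515521 to 7609486 for Western placebo, 2117586 to 7752867 for Western rosuvastatin, 4268535 to 14188533 for chow placebo and 3842326 to 12579473 for chow rosuvastatin. At these depths 1 read of a transcript of 2 kb corresponds to 0.035 to 0.236 RPKM. Reads without molecular identifiers are not independent molecules, so this step covers counting error only.

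Genes with at least 1 RPKM in at least 4 libraries were tested, 12650 in all. Values were transformed to log2 of RPKM plus 1, and all 21 libraries were fitted together with limma 3.58.1 (limma-trend with robust empirical Bayes, statmod 1.5.0) in R 4.3.3. The fit had 4 group means. The comparisons were rosuvastatin against placebo on each diet, Western diet against chow under each agent, and the difference between the effects of rosuvastatin on the 2 diets (the interaction). P values were adjusted over all tested genes by the method of Benjamini and Hochberg, and a gene was called at an adjusted p under 0.05. Fold changes printed relative to the median of all genes are the fitted values minus that median, while their adjusted p values test the fitted values against 0. Errors of log2 fold changes are standard errors from this fit, and errors of RPKM values are SD between libraries.

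A set of 31 gene lists, 471 genes in all, was fixed before the data were examined, and 470 of these genes are in the table. Of the lists, 28 had at least 4 tested members. The lists of neutrophil, exocrine pancreas and skeletal muscle genes had 3, 2 and 2 tested members and were not tested. Lists were tested with camera at a preset correlation between genes of 0.01, and again with an estimated correlation and with fry. Camera compares a list with all other genes, while fry asks whether its members move, on balance, in 1 direction and compares it with no other genes. Counts of list members were also taken with p values adjusted over the list alone.

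Genes named in the text were chosen by a rule fixed before the data were examined. For each comparison these were the 8 genes with the smallest p among those higher and the 8 among those lower, from the called genes averaging at least 1 RPKM, or, where fewer than 4 genes passed, the 4 with the smallest p. To these were added up to 3 members per list with the smallest p, and always Ldlr, Igf2, Apob, Hmgcr, Pcsk9 and Sqle. The text names some of these. 1700037C18Rik, and Idi1 and Cyp51 on chow, were named after their values were seen. The values of Malat1, Neat1, Rn45s, Xist, Hba-a1, Cfd, Arntl and Dbp were also picked after the values were seen.

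Alternatives fixed before the data were examined were no filter except all zeros, a minimum of 5 RPKM, pseudocounts of 0.1 and 10, a test against a fold of 1.2, the replicate number as a block, each library left out in turn, only the compared groups in the fit, and the other list tests. For the lists, the minimum of 5 RPKM, both pseudocounts and the fit with only the compared groups were added after the data were seen. Alternatives chosen after the data were seen were median-ratio and upper-quartile scaling of the RPKM values, voom on the reads recovered from the RPKM steps, 1 quality weight per diet, removal of a trend with transcript length, and fits without the libraries highest in Rn45s or in Hba-a1. Voom used library sizes set by median-ratio scaling and 1 quality weight per library. Planned tests that need deposited read counts were not run, because the table holds RPKM.

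The pipeline was tested on simulated reads for 12256 genes with 200 genes changed in each rosuvastatin comparison before the filter. On the Western diet it recovered 35.4%, 87.7% and 98.4% of the 65, 65 and 64 tested genes changed by folds of 1.5, 2 and 4, with 41 false calls among 12062 unchanged genes. On chow it recovered 36.4%, 91.0% and 98.5% of 66, 67 and 66 (24, 61 and 65 genes), with 1 false call among 12057. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Coordinates are those of the table on mm9 and were not compared with any other build.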

Results

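Liver RNA was profiled in 21 mice labelled as lacking the LDL receptor, fed Western diet or chow and given placebo or rosuvastatin. The series asks what rosuvastatin does in such mice, in which, per that label, uptake through the receptor is missing. Of the 22796 genes in the table, 12650 were tested. The first principal component of the tested genes held 65.4% of the variance and separated the diets. Fold changes of genes are limma estimates with their standard error. For rosuvastatin on chow they are given as fitted, and in the other comparisons the median of all tested genes was subtracted. The adjusted p value of a gene always tests the fitted value, before that subtraction. RPKM values are means ± SD over the libraries of a group.

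The genes that define the strain were read first. Ldlr (NM_001252658, mm9 chromosome 9, 21528020 to 21554362) had 9.40 ± 4.52 RPKM in Western placebo (n = 4), 9.21 ± 2.50 in Western rosuvastatin (n = 6), 4.08 ± 1.08 in chow placebo (n = 5) and 3.02 ± 0.84 in chow rosuvastatin (n = 6). The table gives 1 value per gene, so reads outside the deleted part count and the value does not check the knock-out label. Apob (NM_009693, mm9 chromosome 12) had 483 ± 131, 457 ± 67.3, 253 ± 36.1 and 246 ± 58.5 RPKM in the same order. Igf2 (NM_001122737, mm9 chromosome 7) averaged 0.487, 0.544, 0.237 and 0.127 RPKM, with no library above 1.26, and was under the filter. Only liver was profiled, so these values do not check the IGF-II part of the genotype label. Hmgcs1 is listed at 0 in every library. Xist was at or under 0.278 RPKM and the Y-linked Ddx3y between 24.6 and 60.8 RPKM in every library.

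On the Western diet, livers of mice given rosuvastatin had higher RNA of some of the enzymes that make cholesterol than livers of mice given placebo. Several genes of glutathione and drug metabolism rose, and so did genes of the collagen matrix and of cell division. Genes of the acute phase, of glucose handling, of male liver and of periportal hepatocytes were called lower as groups by the test with a preset correlation. No list was called on this diet with an estimated correlation, where the smallest adjusted p was 0.068, nor in the Western groups alone, where it was 0.147. Library by library, the height of the sterol response varied among the 6 treated mice.

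In numbers, 828 of the 12650 genes were called on the Western diet, 715 higher (86.4%) and 113 lower, and 3106 had an unadjusted p under 0.05. Among the called genes 125 were more than 2-fold higher and 33 more than 2-fold lower. The median log2 fold change of all tested genes was 0.13, and the fold changes of genes and lists on this diet are given relative to that median. After median-ratio scaling the median was -0.01 and the split was 193 higher and 206 lower of 399 genes, of which 302 were among the 828. Single genes were followed through the alternatives for a selection of those that the naming rule gave, not for all of them. Of the 40 called genes in that selection, 34 were called after that scaling, and Cyp51, Lss, Hmgcr, Scd2, Fgf21 and Epcam were not. After upper-quartile scaling the split was 266 higher and 148 lower of 414. Voom on recovered reads called 23 higher and 55 lower.

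In simulated data false calls on the Western diet were a larger share of all calls than the threshold of 0.05 allows. There were 41, beside 23, 57 and 63 true calls at folds of 1.5, 2 and 4. The fit shares 1 spread per gene over both diets, and libraries spread more on the Western diet (residual SD 0.303) than on chow (0.209). With 1 quality weight per diet 163 genes were called, all among the 828. The count on the Western diet also depends on single libraries. It was 194 without Western placebo 2, 1277 without Western placebo 1, 381 without Western rosuvastatin 4, 474 without Western rosuvastatin 6 and 1344 without Western rosuvastatin 5. Fitted without the chow groups, no gene was called by limma, with 2059 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.0512. In the full data limma called 828 genes, or 399 after median-ratio scaling. Voom called 78, with such scaling and a quality weight per library, so the fall cannot be laid to the test alone. Without the 3 libraries above 5000 RPKM of the haemoglobin gene Hba-a1 (Western placebo 2 and 4, chow rosuvastatin 4), 20 genes were called, 19 of them among the 828. Of the 40 selected genes 5 kept their call: Tinag, Cbr3, Hand2, Cyp2c37 and Tpx2.

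Of the 19 tested genes of cholesterol synthesis, the pathway that the statin's target feeds, 6 rose and none fell on the Western diet. Adjusted over the list alone, 13 rose. All 19 lay above the median of all genes, and the list's median was 1.06 above it on the log2 scale (camera adjusted p = 2.3e-06, adjusted p = 0.34 with an estimated correlation, fry adjusted p = 0.044). In the Western groups alone 0 of the 19 passed limma's test adjusted over the list alone, and fry gave an adjusted p of 0.21. Idi1, isopentenyl diphosphate isomerase (NM_145360, mm9 chromosome 13, 8884852 to 8891642), had 277 ± 286 RPKM with rosuvastatin (n = 6) and 28.7 ± 10.99 with placebo (n = 4). Its log2 change was 2.48 ± 0.57 (adjusted p = 0.014), and 5 of 6 treated libraries were above every placebo library. Hmgcr, the statin's target (NM_008255, mm9 chromosome 13, 97418919 to 97440891), had 95.7 ± 116 against 15.3 ± 3.54 RPKM, a log2 change of 1.76 ± 0.55 (adjusted p = 0.045). Sqle did not pass (1.38 ± 0.49, adjusted p = 0.070), nor did Pcsk9 (0.33 ± 0.35, adjusted p = 0.43), Ldlr (-0.10 ± 0.23, fitted 0.04, adjusted p = 0.94) or Apob (-0.18 ± 0.19, adjusted p = 0.91).

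The sterol genes differed widely among the treated Western mice. Western rosuvastatin 2 had 322 RPKM of Hmgcr and 759 of Idi1, while Western rosuvastatin 1 had 16.9 and 37.1. The list's median was 0.65 without Western rosuvastatin 2. The call of Idi1 was lost without Western placebo 2 (adjusted p = 0.062). The call of Hmgcr was lost in 15 of the 21 omissions of 1 library, with adjusted p values up to 0.135 (without Western placebo 2), and also after median-ratio scaling or removal of a trend with transcript length.

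Of 26 tested genes of drug and glutathione metabolism, which modify foreign compounds, 9 rose and 1 fell. Adjusted over the list alone, 11 rose and 2 fell. The list's median was 0.19 above that of all genes (camera adjusted p = 0.016, adjusted p = 0.34 with an estimated correlation, fry adjusted p = 0.0093), and it was 0.33, 0.34 and 0.29 without Western placebo 1, Western placebo 3 and Western rosuvastatin 1. Without the 3 libraries highest in Hba-a1 camera gave an adjusted p of 0.141, and in the Western groups alone fry gave one of 0.110, with 10 genes higher and 1 lower adjusted over the list alone. Gstm3 (NM_010359, mm9 chromosome 3, 107766614 to 107772092) had 421 ± 316 RPKM against 29.0 ± 14.7, a log2 change of 3.39 ± 0.49 (adjusted p = 0.0011), and Gsta2 had 37.3 ± 19.6 against 5.40 ± 5.33 (2.58 ± 0.39, adjusted p = 0.0011). Cyp2c37 (NM_010001, mm9 chromosome 19) fell from 102.5 ± 25.5 to 35.9 ± 10.3 RPKM (-1.63 ± 0.21, adjusted p = 0.0011). These genes belong to families of similar sequence, so their values are uncertain for shared reads. Cbr3, a carbonyl reductase, had 18.8 ± 13.8 against 0.490 ± 0.454 RPKM (3.26 ± 0.45, adjusted p = 8.4e-04), and Abcc4, an exporter of conjugates, had 5.499 ± 2.96 against 0.817 ± 0.332 (1.58 ± 0.25, adjusted p = 0.0011). Reads shared with related genes were not examined for these either. Tinag (NM_012033, mm9 chromosome 9), a basement membrane gene, had the smallest p, 6.76 ± 3.43 against 0.632 ± 0.435 RPKM (2.05 ± 0.26, adjusted p = 2.1e-04), with 6 of 6 treated libraries above every placebo library.

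Of 18 tested genes of fibrosis and stellate cells, the matrix-making cells of liver, 8 rose and none fell, and adjusted over the list alone 13 rose. The list's median was 0.56 above that of all genes (camera adjusted p = 1.7e-06, adjusted p = 0.14 with an estimated correlation, fry adjusted p = 0.0068). Col3a1 (NM_009930, mm9 chromosome 1) had 40.4 ± 20.3 RPKM with rosuvastatin (n = 6) and 13.4 ± 3.79 with placebo (n = 4), a log2 change of 1.30 ± 0.28 (adjusted p = 0.0068). Of 11 genes of the cell cycle, 8 rose, and adjusted over the list alone all 11 rose. The median was 0.85 above that of all genes (camera adjusted p = 2.5e-08, adjusted p = 0.068 with an estimated correlation, fry adjusted p = 2.6e-04). Mki67 (NM_001081117, mm9 chromosome 7), present in dividing cells, had 6.36 ± 2.57 against 1.81 ± 1.07 RPKM (1.24 ± 0.25, adjusted p = 0.0037), and Top2a changed by 1.47 ± 0.27 (adjusted p = 0.0024). Of 6 bile duct genes 2 rose, Spp1 among them (0.97 ± 0.22, adjusted p = 0.0068). The median was 0.53 above that of all genes (camera adjusted p = 0.036, adjusted p = 0.34 with an estimated correlation). That call was lost without Western placebo 1 or 2 or Western rosuvastatin 1, 4 or 5 (adjusted p = 0.084, 0.103, 0.056, 0.086 and 0.108), and the median was 0.23 without Western rosuvastatin 4 and 0.35 without Western placebo 2. Endothelial genes were not called (-0.10, camera adjusted p = 0.28). In the Western groups alone, fry gave an adjusted p of 0.110 for the fibrosis list and 0.043 for the cell cycle list, with 12 and 10 genes higher adjusted over the list alone.

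Of 21 acute-phase genes, which the liver secretes in inflammation, 4 fell and none rose, and adjusted over the list alone 8 fell. The median was 0.57 under that of all genes (camera adjusted p = 2.1e-10, adjusted p = 0.068 with an estimated correlation, fry adjusted p = 0.019). Itih4 changed by -1.10 ± 0.18 (adjusted p = 0.0044) and Saa3 by -1.35 ± 0.25 (adjusted p = 0.0068), the latter from a family with shared sequence. In the Western groups alone 5 acute-phase genes were lower adjusted over the list alone, and fry gave an adjusted p of 0.145. Of 22 genes of glucose and insulin handling 4 fell, and adjusted over the list alone 4 fell (camera adjusted p = 1.3e-06, adjusted p = 0.068 with an estimated correlation), while 1 was lower adjusted over the list alone in the Western groups alone. Khk, which phosphorylates fructose, went from 269 to 160.5 RPKM (-0.89 ± 0.16, adjusted p = 0.010). The interferon list had 3 of 19 genes higher (camera adjusted p = 0.015, adjusted p = 0.41 with an estimated correlation). Its call was lost without Western placebo 4 (adjusted p = 0.103) or Western rosuvastatin 6 (adjusted p = 0.076), and its median of 0.25 above all genes was 0.39 without Western placebo 1 and 0.43 without Western rosuvastatin 1.

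In lipid metabolism on the Western diet, the list of fatty acid synthesis had 1 gene higher and 1 lower of 25, by all genes and by the list alone, with a median 0.44 under that of all genes (camera adjusted p = 5.6e-06, adjusted p = 0.14 with an estimated correlation). Cidea (NM_007702, mm9 chromosome 18), a lipid droplet gene, fell from 13.6 ± 7.04 RPKM with placebo (n = 4) to 2.28 ± 1.801 with rosuvastatin (n = 6), a log2 change of -2.33 ± 0.50 (adjusted p = 0.016), with 6 of 6 treated libraries under every placebo library. Of 22 bile acid genes 2 fell (camera adjusted p = 3.5e-04, adjusted p = 0.10 with an estimated correlation). Of 19 lipoprotein genes none was called, with 0 over the list alone, and the list's median was 0.19 under that of all genes (camera adjusted p = 0.0084, adjusted p = 0.10 with an estimated correlation, fry adjusted p = 0.28) and 0.28 under it without Western placebo 4. Fatty acid oxidation genes were not called (camera adjusted p = 0.057).

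Of 13 genes higher in male than in female liver, 2 fell, and adjusted over the list alone 4 fell, or 1 in the Western groups alone (median 0.84 under all genes, camera adjusted p = 2.5e-08, adjusted p = 0.10 with an estimated correlation). Cyp2a4, one of 5 tested genes higher in females, had 237 ± 200 against 35.7 ± 11.7 RPKM (2.20 ± 0.48, adjusted p = 0.0096) and is uncertain for reads shared within its family. The female list was not called (camera adjusted p = 0.088). Among genes of hepatocyte zones, 2 of 12 periportal genes fell (median 0.49 under all genes, camera adjusted p = 9.4e-07, adjusted p = 0.068 with an estimated correlation). In the pericentral list 2 of 13 rose and 3 fell (camera adjusted p = 0.0069, adjusted p = 0.14 with an estimated correlation), and the median of 0.18 under all genes was 0.35 under them without Western placebo 1. Glul (NM_008131, mm9 chromosome 1), glutamine synthetase of pericentral cells, fell from 688 ± 64.4 to 378 ± 90.3 RPKM (-1.02 ± 0.17, adjusted p = 0.0062). Circadian genes as a list were lower (median 0.21 under all genes, camera adjusted p = 0.012, adjusted p = 0.21 with an estimated correlation), which was lost without Western placebo 2 (0.12 under, adjusted p = 0.125) and after median-ratio scaling (adjusted p = 0.079), and the median was 0.33 under all genes without Western placebo 4 and 0.13 under them without Western rosuvastatin 1.

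The red cell and fat lists moved with a few placebo libraries on the Western diet. Hba-a1 had 6385 ± 5138 RPKM in Western placebo (n = 4), with 12940 in Western placebo 4 and 7978 in Western placebo 2, and 2012 ± 1286 in Western rosuvastatin (n = 6). Of 7 red cell genes 1 fell, by all genes and by the list alone, while in the Western groups alone all 7 were lower adjusted over the list alone. The list's median was 1.57 under all genes (camera adjusted p = 4.1e-06, adjusted p = 0.14 with an estimated correlation). Of 4 fat cell genes 1 fell (median 0.73 under all genes, camera adjusted p = 0.018, adjusted p = 0.11 with an estimated correlation), and without Western placebo 4 the median was 0.03 under all genes (adjusted p = 0.253). Without Western placebo 2 it was 1.18 under them.

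**Figure D1:**
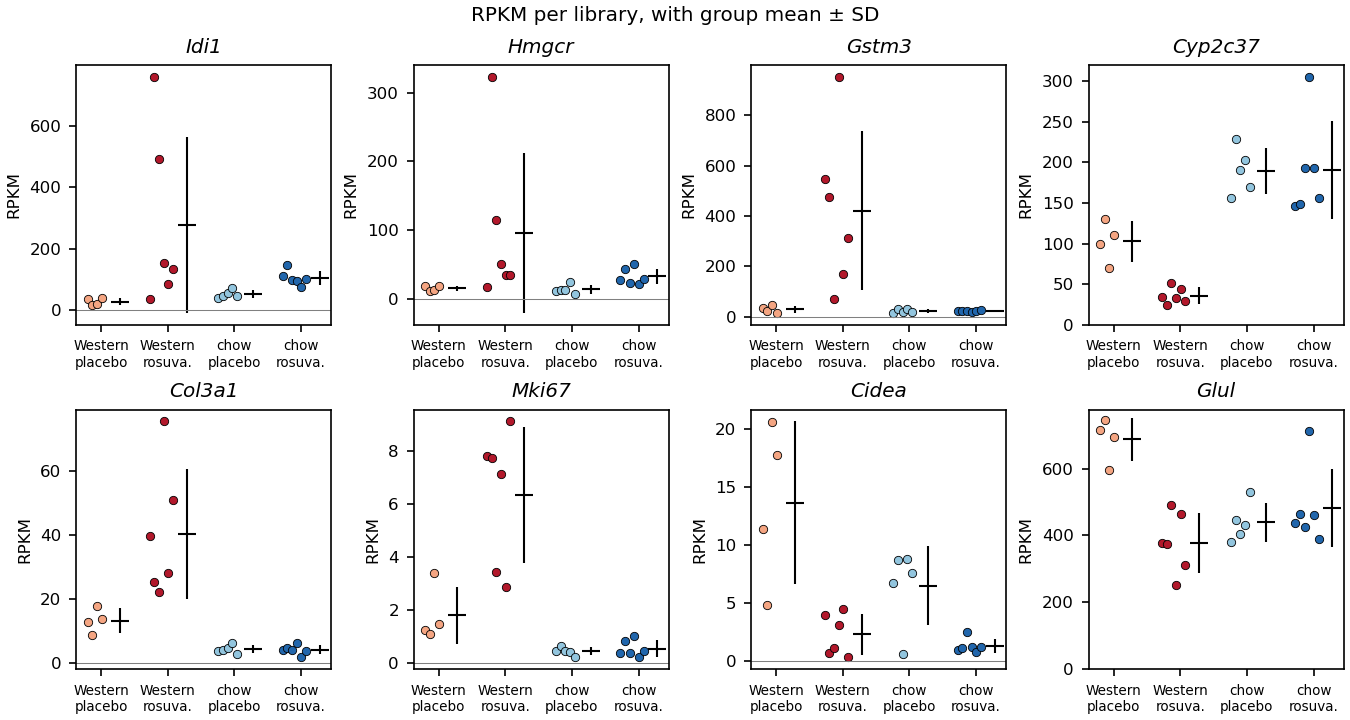
RPKM of 8 genes in each of the 21 libraries, by diet and agent, with the mean and SD of each group. Idi1 and Hmgcr spread widely among the 6 Western rosuvastatin libraries, while every one of these libraries was under every Western placebo library for Cidea.

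On chow, limma fitted to all libraries called no gene for rosuvastatin, and fitted to the chow groups alone it called 4. The genes of cholesterol synthesis nevertheless stood apart as a group, all of them above the middle of the genes tested. These genes were called at the preset correlation and not with an estimated one (adjusted p = 0.56).

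With limma 0 of 12650 genes were called on chow, with 227 at an unadjusted p under 0.05, and voom also called 0, with 713 at an unadjusted p under 0.05. With 1 quality weight per diet limma called 0 as well, with 608 at an unadjusted p under 0.05. Fitted with the chow groups alone, limma called 4 genes, all higher: Scd2, Sqle and Mvk (adjusted p = 0.0218 each) and Cyp51 (adjusted p = 0.0333). The spread between libraries was smaller on chow, with a residual SD of 0.209 against 0.303 on the Western diet. In simulated data of this size, where all genes of a diet had the same dispersion, the fit recovered 91.0% of the genes that differed 2-fold on chow. The real fit shares 1 spread per gene over both diets, and genes that spread widely on the Western diet were not simulated. For Sqle on chow the standard error was 0.46 in that fit and 0.18 in the chow groups alone, so the recovered share may not hold.

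Sqle (NM_009270, mm9 chromosome 15), squalene epoxidase, had 35.1 ± 8.52 RPKM with rosuvastatin on chow (n = 6) and 13.9 ± 3.87 with placebo (n = 5), with 6 of 6 treated libraries above every placebo library. Its log2 difference of 1.28 ± 0.46 did not pass in the full fit (adjusted p = 1), nor did those of Mvk (1.16 ± 0.45, 31.8 ± 10.5 against 13.2 ± 1.96 RPKM), Hmgcr (1.19 ± 0.52, 32.5 ± 11.5 against 13.9 ± 6.10 RPKM) and Cidea (-1.52 ± 0.47). Idi1 (0.98 ± 0.53) and Cyp51 (1.18 ± 0.53), named after their values were seen, did not pass either. The 4 smallest p values belonged to Spink1 (1.34 ± 0.35), Nsfl1c (-0.38 ± 0.10), Mtmr11 (0.64 ± 0.18) and Shkbp1 (0.52 ± 0.15), none of which passed (adjusted p = 1). Ldlr (-0.33 ± 0.22) and Pcsk9 (0.30 ± 0.32) did not pass.

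On chow, 19 of 19 cholesterol synthesis genes lay above the median of all genes, and the list's median was 0.70 above it (camera adjusted p = 1.0e-19, adjusted p = 0.56 with an estimated correlation, fry adjusted p = 0.99). Adjusted over the list alone none of its genes passed, with limma in the full fit. In the chow groups alone 17 of the 19 passed adjusted over the list alone, with an adjusted p of 0.058 for the list with an estimated correlation and 0.044 with fry. The acute-phase list was 0.13 under all genes (camera adjusted p = 0.016, adjusted p = 0.83 with an estimated correlation, fry adjusted p = 0.99). Its call was lost without chow placebo 1 (adjusted p = 0.334, median 0.08 under all genes), chow rosuvastatin 3 (adjusted p = 0.058) or chow rosuvastatin 4 (adjusted p = 0.0505).

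**Figure D2:**
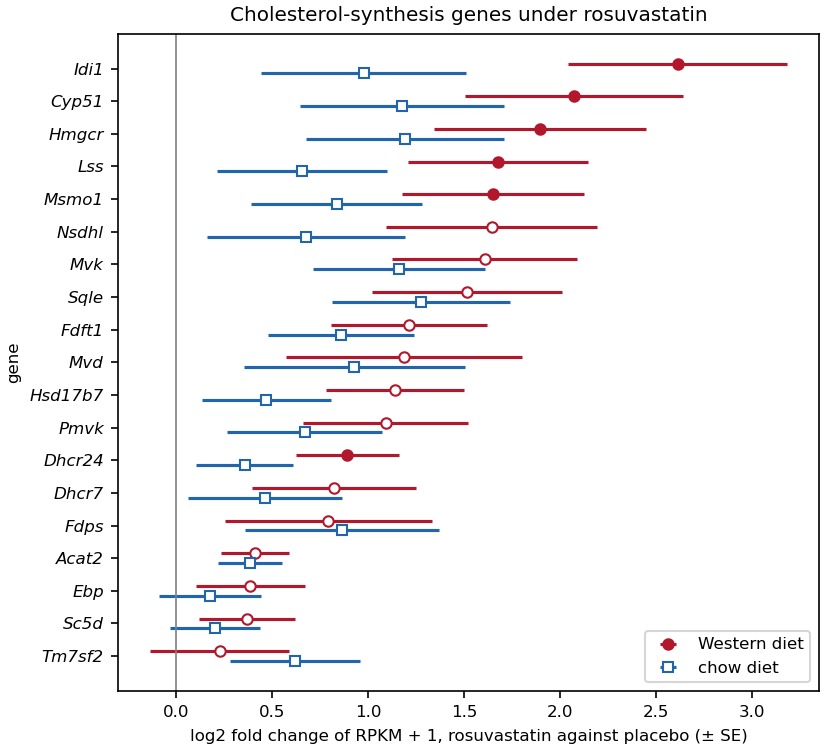
Fitted log2 fold change with its standard error for rosuvastatin against placebo of the 19 tested cholesterol synthesis genes, on the Western diet (red circles) and chow (blue squares), with filled symbols for an adjusted p under 0.05. Of the 19 genes, 6 are filled on the Western diet and none on chow.

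Whether rosuvastatin acted differently on the 2 diets was tested directly. At the level of genes a single one passed, so most of what was called on the Western diet alone is not shown to differ between diets. Several gene groups, those of the matrix and of cell division among them, were called at a preset correlation, but no group was with an estimated correlation, where the smallest adjusted p was 0.092. The cholesterol synthesis genes were not shown to differ.

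The interaction called 1 of 12650 genes, with 1807 at an unadjusted p under 0.05, and the median of all genes was 0.16. The gene, 1700037C18Rik (NM_028484), named after its values were seen, had 0.440 ± 0.215, 2.00 ± 0.489, 0.789 ± 0.166 and 0.299 ± 0.132 RPKM in Western placebo, Western rosuvastatin, chow placebo and chow rosuvastatin, an interaction of 1.36 ± 0.20 relative to the median (adjusted p = 0.0011). Voom ended that call (adjusted p = 0.151), as did leaving out the 3 libraries highest in Hba-a1 (adjusted p = 0.112), and at a minimum of 5 RPKM the gene was not tested. The count was 150 without Western placebo 1, 69 without Western rosuvastatin 3, 63 without Western rosuvastatin 5, 7 without Western placebo 3, 3 without Western rosuvastatin 2, 2 without Western rosuvastatin 1 and 2 without chow rosuvastatin 3. Gstm3 (3.35 ± 0.68), Gsta2 (2.56 ± 0.53) and Cyp2c37 (-1.63 ± 0.29) did not pass (adjusted p = 0.080 each), nor did Idi1 (1.48 ± 0.78, adjusted p = 0.35) or Hmgcr (0.55 ± 0.76, adjusted p = 0.70). Gstm3 and Gsta2 passed without Western placebo 1 (adjusted p = 0.040 and 0.0014), Western rosuvastatin 3 (adjusted p = 0.0012 and 0.0088) or Western rosuvastatin 5 (adjusted p = 0.035 and 0.036). Cyp2c37 passed without each of these (adjusted p = 0.040, 0.017 and 0.035) and without Western placebo 3 (adjusted p = 0.033).

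Camera called 15 lists for the interaction, fry called 1, and none was called with an estimated correlation. Relative to all genes the medians were 0.63 for fibrosis, 0.68 for the cell cycle, -0.43 for glucose handling, -0.45 for the acute phase and -0.79 for male-biased genes. The cholesterol synthesis list was not called (camera adjusted p = 0.59) but was without Western rosuvastatin 1 (median 0.50, adjusted p = 0.0092).

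**Figure D3:**
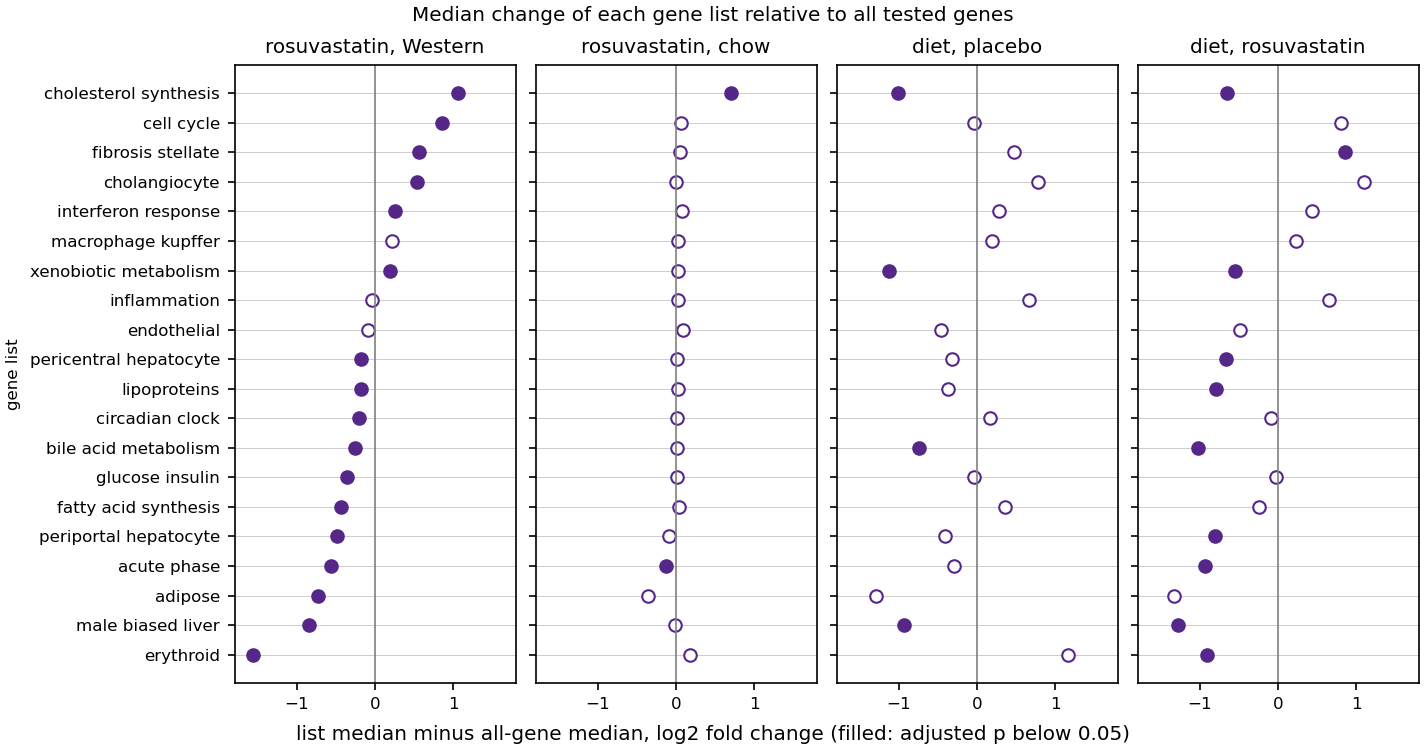
Median log2 fold change of 20 gene lists minus the median of all tested genes in the comparisons of rosuvastatin with placebo and of Western diet with chow, with filled symbols for a camera adjusted p under 0.05. The cholesterol synthesis list lies 1.06 and 0.70 above all genes for rosuvastatin and 1.01 and 0.65 under them for the Western diet.

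Between the diets most genes differed. In placebo mice on Western diet, genes that make bile acids, metabolise drugs and make cholesterol were called lower as groups than on chow at a preset correlation. In the fit with all libraries none of these groups was called with an estimated correlation (adjusted p = 0.136, 0.136 and 0.673), while with only the compared groups the bile acid genes were (adjusted p = 0.027). Most of the tested genes of sterol efflux, of inflammation and of the matrix rose, beside 6002 of all 12650 tested genes. Camera called none of these groups without a change of scaling. The diets differed as well in nuclear RNAs, in transcript length and in depth. The labels name no batch and give no age for the Western-diet mice, so diet cannot be told apart from a batch or from age.

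In placebo mice 7440 of 12650 genes were called, 6002 higher on the Western diet (80.7%) and 1438 lower. By the fitted value, with no median subtracted, 2024 and 397 of these changed at least 2-fold. The median log2 fold change was 0.40, and those of genes and lists are given relative to it. Of 29 called genes selected from those that the naming rule gave, 27 were called after median-ratio scaling. After median-ratio scaling 6521 genes were called, 50.7% of them higher, and 4745 of the 7440 kept their call and direction. The log2 fold change rose with transcript length across genes, which are not independent replicates (Spearman's rho = 0.411). After removal of that trend 5427 genes were called, 49.9% of them higher. Malat1, a nuclear RNA, had 929 ± 260 and 1098 ± 144 RPKM on Western placebo and rosuvastatin, and 207 ± 29.7 and 201 ± 56.1 on chow. Neat1 had 272 ± 60.3, 297 ± 36.7, 68.2 ± 20.3 and 63.3 ± 13.4 RPKM in that order, and the ribosomal precursor Rn45s had medians of 119, 299, 18.7 and 14.2 RPKM.

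Of 22 bile acid genes 9 fell and 3 rose on the Western diet with placebo (median 0.75 under all genes, camera adjusted p = 4.7e-05, adjusted p = 0.14 with an estimated correlation, fry adjusted p = 0.0010). Cyp8b1 (NM_010012, mm9 chromosome 9), which sets the share of cholic acid, had 33.8 ± 10.0 RPKM on Western diet (n = 4) and 190 ± 45.3 on chow (n = 5), a log2 change of -2.87 ± 0.33 (adjusted p = 2.8e-06). Of 26 drug metabolism genes 12 fell and 4 rose (median 1.13 under all genes, camera adjusted p = 5.7e-07, adjusted p = 0.14 with an estimated correlation). Ces2a, a carboxylesterase, changed by -2.46 ± 0.21 (adjusted p = 5.2e-08). Of 19 cholesterol synthesis genes 5 fell, 3 adjusted over the list alone (median 1.01 under all genes, camera adjusted p = 1.8e-04, adjusted p = 0.67 with an estimated correlation, fry adjusted p = 0.32). With only the compared groups 10 fell, also 10 adjusted over the list alone (adjusted p = 0.54 with an estimated correlation, fry adjusted p = 0.042). Msmo1 changed by -2.64 ± 0.49 (adjusted p = 6.8e-04), while Hmgcr (-0.20 ± 0.57, adjusted p = 0.79) and Sqle (-1.01 ± 0.51, adjusted p = 0.31) did not pass. In the male-biased list 3 of 13 genes rose and 5 fell (camera adjusted p = 0.027, adjusted p = 0.67 with an estimated correlation), and the call was lost without Western placebo 3 (adjusted p = 0.081), Western placebo 4 (adjusted p = 0.076) or chow placebo 5 (adjusted p = 0.061, median -0.63 against -0.94). It was also lost after each change of scaling, at a minimum of 5 RPKM (adjusted p = 0.092), with the replicate block (adjusted p = 0.052) and after removal of the trend with length (adjusted p = 0.397).

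Of 12 genes listed for sterol efflux and the oxysterol receptor LXR, the receptor genes Nr1h3 and Nr1h2 among them, 10 rose and 1 fell (camera adjusted p = 0.12, fry adjusted p = 1.9e-07). Over all 12650 tested genes 6002 rose, with a median of 0.40, and fry, unlike camera, takes in that rise. Abcg5 had 43.7 ± 13.1 RPKM on Western diet and 12.7 ± 2.03 on chow with placebo, a log2 change of 1.27 ± 0.23 (adjusted p = 2.7e-06). Of 17 inflammation genes 13 rose (camera adjusted p = 0.13, fry adjusted p = 9.2e-05), and of 18 fibrosis genes 13 rose (camera adjusted p = 0.13). After median-ratio scaling camera called both (adjusted p = 0.036 and 0.040). Col1a2 had 17.8 ± 8.25 against 3.00 ± 0.824 RPKM (1.76 ± 0.33, adjusted p = 1.3e-05) and Apoa4, an apolipoprotein, 1238 ± 569 against 158 ± 64.3 (2.52 ± 0.34, adjusted p = 4.7e-07). Of 19 lipoprotein genes 6 rose and 7 fell, with a median 0.37 under all genes, and the list was not called. Apoa2 (-3.03 ± 0.23, adjusted p = 6.3e-09) and Cox7a2 (-2.51 ± 0.13, adjusted p = 1.5e-10), with short transcripts of 515 and 748 bases, were lower, and Cmip, with 4328 bases, was higher (2.51 ± 0.17, adjusted p = 9.7e-11). These 3 stayed called after removal of the trend with length. Ldlr (fitted 0.96 ± 0.24, adjusted p = 0.0015) and Apob (fitted 0.89 ± 0.20, adjusted p = 5.5e-04) were called, and lay 0.57 and 0.50 above the median of all genes, but not after median-ratio scaling (adjusted p = 0.061 and 0.080) or removal of the trend with length (adjusted p = 0.214 and 0.657), where the sign of Apob turned (fitted -0.09).

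**Figure D4:**
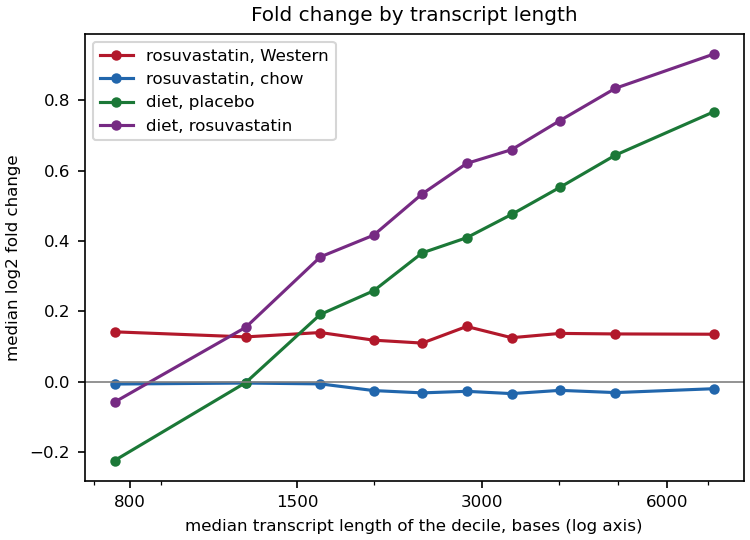
Median log2 fold change of the tested genes in 10 bins of transcript length (log axis, bases) for 4 comparisons. The medians of both diet comparisons rise with length (Spearman's rho across genes = 0.411 and 0.384), while those of rosuvastatin on the Western diet do not (rho = 0.0055).

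In rosuvastatin mice, too, most genes differed between the diets. Bile acid genes were called lower on the Western diet at a preset correlation. With an estimated correlation they were called in the fit with all libraries (adjusted p = 0.036) and not with only the compared groups (adjusted p = 0.113). Acute-phase and male-biased genes were called lower at the preset correlation and not with an estimated one (adjusted p = 0.22 and 0.24). Every fibrosis gene tested rose, beside 7868 of all 12650 tested genes.

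In numbers, 9324 of 12650 genes were called, 7868 higher (84.4%) and 1456 lower. By the fitted value, with no median subtracted, 3158 and 399 of these changed at least 2-fold. The median was 0.57, and the fold changes of genes and lists below are relative to it. Of 20 called genes selected from those that the naming rule gave, 18 were called after median-ratio scaling. After median-ratio scaling 8008 genes were called, 51.6% of them higher. Of 22 bile acid genes 14 fell and 4 rose (median 1.03 under all genes, camera adjusted p = 3.8e-08), the single list called with an estimated correlation in the fits with all libraries (adjusted p = 0.036). Of 18 fibrosis genes 18 rose (median 0.86 above all genes, camera adjusted p = 0.0028, adjusted p = 0.59 with an estimated correlation). Col1a2 had 44.8 ± 25.3 RPKM on Western diet (n = 6) and 3.33 ± 0.947 on chow (n = 6), a log2 change of 2.70 ± 0.28 (adjusted p = 2.3e-09). Of 21 acute-phase genes 10 fell and 4 rose (camera adjusted p = 1.0e-05, adjusted p = 0.22 with an estimated correlation), and of 13 male-biased genes 7 fell and 1 rose (camera adjusted p = 1.0e-05, adjusted p = 0.24 with an estimated correlation), with Mup7 at 257 against 12430 RPKM (-6.36 ± 0.66, adjusted p = 2.8e-07), uncertain for reads shared in its family.

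Of the other lists called in rosuvastatin mice, lipoproteins had 7 genes higher and 8 lower of 19 (camera adjusted p = 0.0024, adjusted p = 0.11 with an estimated correlation), drug metabolism 11 and 10 of 26 (camera adjusted p = 5.7e-04, adjusted p = 0.24 with an estimated correlation), pericentral genes 3 and 5 of 13 (camera adjusted p = 0.0020, adjusted p = 0.22 with an estimated correlation) and periportal genes 2 and 5 of 12 (camera adjusted p = 5.7e-04, adjusted p = 0.22 with an estimated correlation). The first of these lost its call after removal of the trend with length (adjusted p = 0.080), as did drug metabolism (adjusted p = 0.150). Cholesterol synthesis had 1 gene higher and 5 lower of 19 (median 0.65 under all genes, camera adjusted p = 0.0014, adjusted p = 0.60 with an estimated correlation). That median was 1.04 under all genes without Western rosuvastatin 2 and 0.36 under them without Western rosuvastatin 1, and the call was lost after median-ratio scaling (adjusted p = 0.0503) or removal of the trend with length (adjusted p = 0.081). Red cell genes were called lower (median 0.91 under all genes, camera adjusted p = 0.012, adjusted p = 0.59 with an estimated correlation), but not without chow rosuvastatin 4 (0.11 under, adjusted p = 0.111) nor after any change of scaling. Hmgcr did not pass (0.32 ± 0.49, adjusted p = 0.11), though it did without Western rosuvastatin 1 (adjusted p = 0.018).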

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

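Among the tests in this part, those of the libraries' depth, of scaling for the fibrosis and cell-cycle genes and of other splits of the samples were set before their results were seen. So were the gene and list calls of the main fit, also with each library left out. The remaining tests were chosen only after the result was seen.

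The first pattern weighed is that 7440 genes differed between the diets in placebo mice. Scaling to library totals as the whole cause is argued against by 63.78% of these genes being called in the same direction after median-ratio scaling. After each library's trend with transcript length was removed, 51.17% were called in the same direction and 105 in the opposite direction. The cut, that most of the called genes keep call and direction, was set after the data were seen, and 51.17% barely passes it. It argues only weakly against that trend alone as the whole cause. A bias that the trend does not describe would remain after its removal, so a bias tied to length stays open. The excess of genes higher, 80.67%, was 50.71% after median-ratio and 60.82% after upper-quartile scaling, so whether it came from the scaling cannot be told apart from a wider rise in RNA, because each scaling assumes its own middle. A library batch that follows the diets cannot be told apart from diet, since the labels name none, and the log2 fold change correlated with transcript length across genes (Spearman's rho = 0.4114). Age cannot be told apart from diet either, since the labels give none for the Western-diet mice. Diet itself stays open as untested.

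The second pattern weighed is the spread of cholesterol synthesis genes among the 6 Western rosuvastatin libraries. A wrong label on Western rosuvastatin 1, whose sterol genes were at the placebo level, cannot be excluded. Of 553 other genes called without it, 85.35% lay on the rosuvastatin side in it. But of all 565 genes called without it, 482 were higher with rosuvastatin. Its median-ratio factor was 1.381, against 1.118 to 1.205 in Western placebo, so a rise of all its values could give such a share. The measure was not repeated after scaling. The same measure gave 56.9%, 16.5%, 46.5% and 41.9% in Western placebo 1, 2, 3 and 4, so it parts the labels only roughly, and Western rosuvastatin 1 lay above all 4. Time of day could be the cause, but the difference between the clock genes Dbp and Arntl did not decide it, with Spearman's rho = 0.3143 (exact permutation p = 0.564, adjusted 0.79), Pearson's r = 0.608 (exact permutation p = 0.225, adjusted 0.45) and r = -0.854 without the 2 libraries farthest from the median, so the relation rests on those. Depth cannot be excluded either, with rho = 0.3714 (exact permutation p = 0.497, adjusted 0.79), r = 0.235 (exact permutation p = 0.651, adjusted 0.782) and r = 0.983 without the 2 farthest libraries, over 6 relations in all. No biological explanation was tested, since the labels give none within a group.

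The third pattern weighed is the higher fibrosis and cell-cycle genes with rosuvastatin on the Western diet. Scaling to library totals as the whole cause is argued against by 10 of the 16 called genes still being called and higher after median-ratio scaling, and all 16 still had a positive log2 fold change. A lower share of hepatocytes could raise the genes of every other cell type alike. The fibrosis score minus the endothelial score was 0.175 ± 0.541 with rosuvastatin (n = 6) and -0.555 ± 0.456 with placebo (n = 4), and the exact permutation test (two-sided, 210 splits) gave p = 0.06667, so a lower share cannot be told apart from a change in the matrix-making cells. An effect of rosuvastatin stays open as untested.

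Other splits of the samples into groups of the same sizes were counted for each comparison, 100 each with the real one included. For the 828 genes of rosuvastatin on the Western diet 3 splits gave as many. This argues against chance without excluding it, since the counts were not adjusted for the number of comparisons. The highest other split gave 1606, more genes than the real one, and what set it apart was not tested. The counts of lists below say how many were called and do not test any single list. For the count of 17 lists there 4 splits gave as many and the highest other gave 19, which likewise does not exclude chance. The other splits called a median of 8 lists, so the preset correlation calls many lists without the real grouping. On chow limma called 0 genes (voom 0, unadjusted 227), so that all 100 splits had to give as many and their count says nothing about chance (highest other 12). Chance cannot be excluded for the count of 2 lists on chow, where 84 gave as many, the highest other gave 10 and the median was 4. Only the real split gave as many as the 7440 genes between the diets with placebo (1 split, highest other 5681) or the 9324 with rosuvastatin (1 split, highest other 6440). With 100 splits no smaller share was possible, so this argues against chance without excluding it. Chance cannot be excluded for the counts of lists in these comparisons, 4 with placebo (73 splits, highest other 11, median 4) and 10 with rosuvastatin (48 splits, highest other 21, median 9). For the interaction it cannot be excluded for the 1 gene, where 16 splits gave as many. The highest other split gave 549, and what set it apart was not tested. For the interaction's count of 15 lists 3 splits gave as many (highest other 15), again beside a median of 8 in the other splits. This argues against chance without excluding it.

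The test of the difference between diets singled out 1700037C18Rik, with a fitted interaction of 1.52. It singled out 15 lists, with fitted medians of -0.31 (-0.307) for fatty acid synthesis, 0.0226 for fatty acid oxidation, -0.0857 for bile acids, -0.0800 for lipoproteins, -0.269 for glucose handling, 0.359 for drug metabolism, -0.289 for the acute phase and 0.787 for fibrosis. The rest were -0.0685 for the circadian clock, 0.841 for the cell cycle, -0.636 for male-biased, -0.144 for pericentral and -0.367 for periportal genes, 0.695 for bile ducts and -1.57 for red cells. The median of all genes was 0.156, so the list of fatty acid oxidation has a positive median but lies 0.13 under all genes. That distance was 0.03 and 0.07 without Western placebo 1 and Western rosuvastatin 1, and 0.30, 0.21, 0.20 and 0.22 without Western placebo 2, Western rosuvastatin 2, chow placebo 2 and chow rosuvastatin 4. Its call was lost without Western placebo 1 or 4, Western rosuvastatin 1 or 4, chow placebo 5 or chow rosuvastatin 6 (adjusted p from 0.063 to 0.337). The bile duct call was lost without Western placebo 1, 2 or 3, Western rosuvastatin 1, 4 or 5, chow placebo 3 or 5, or chow rosuvastatin 4, 5 or 6 (adjusted p from 0.053 to 0.129). The circadian call was lost without Western placebo 1 or 2, Western rosuvastatin 1, chow placebo 5 or chow rosuvastatin 5 (adjusted p from 0.052 to 0.173), and drug metabolism without Western placebo 2, chow placebo 2 or chow rosuvastatin 4 (adjusted p from 0.058 to 0.073). Relative to all genes, the drug metabolism median of 0.20 was 0.33 and 0.42 without Western placebo 1 and 3, and the bile duct median of 0.54 was 0.35 and 0.23 without Western placebo 2 and Western rosuvastatin 4. The circadian median of -0.22 was -0.10 without Western placebo 2, and -0.46, -0.43, -0.38 and -0.34 without Western placebo 3, Western placebo 4, Western rosuvastatin 2 and chow placebo 1. The red cell median relative to all genes was -1.72, and -1.10 without chow rosuvastatin 4.

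Single libraries lay far from the others of their group in 19 of 357 group and measure combinations, and chance gives about 5%. In RPKM, Cyp2d40 was 34.6 in Western placebo 1 (others 55.1 to 59.2), Lpl 52.1 in Western placebo 3 (others 23.5 to 24.9) and Cox7a2 114 in Western rosuvastatin 6 (others 156 to 185). On chow, Cidea was 2.47 in chow rosuvastatin 3 (others 0.769 to 1.16) and 0.586 in chow placebo 3 (others 6.74 to 8.83), Saa1 was 715 in chow placebo 1 (others 83.8 to 137) and Lyve1 0.69 in chow placebo 5 (others 3.33 to 5.15). Rn45s was 53.0 in chow placebo 5 (others 16.3 to 21.8). Chow rosuvastatin 4 stood out for Glul at 714 (others 390 to 465) and Lpl at 16.2 (others 5.61 to 7.07). The list means in log2 were 3.99 for macrophages (others 2.99 to 3.32), 3.69 for endothelium (others 3.06 to 3.27) and 11.55 for red cells (others 7.29 to 8.61) in that library. Other list means far from their group were 3.78 for sterol efflux (others 3.98 to 4.05) and 2.96 for endothelium (others 3.20 to 3.27) in chow placebo 5, 8.48 for lipoproteins in Western placebo 2 (others 8.62 to 8.65) and 8.73 in Western rosuvastatin 5 (others 8.45 to 8.53). The list of female-biased genes had 5.26 in Western rosuvastatin 2 (others 3.77 to 4.20), and that of B and plasma cells 2.88 in Western placebo 4 (others 0.60 to 0.84).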

How the results depend on the processing

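Of the alternatives here, both scalings of RPKM, voom, the weight per diet, the trend with length, the omissions by Rn45s or Hba-a1 and the list tests in only the compared groups, at 5 RPKM and with other pseudocounts were chosen after the data were seen. Planned count-based tests, voom on deposited counts and count scalings were not run, because the table holds RPKM. The cause of each change below was not tested, except that fewer libraries or genes enter where groups, libraries or genes are left out.

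Genes called for rosuvastatin on the Western diet, 828, ranged from 194 to 1344 with each library left out. They were 538 at a minimum of 5 RPKM, 38 against a fold of 1.2, 510 with a pseudocount of 0.1, 399 with median-ratio scaling, 414 with upper-quartile scaling, 78 with voom, 163 with a weight per diet, 502 with the length trend removed, 20 without the libraries highest in Hba-a1 and, with limma, 0 with only the compared groups (2059 unadjusted; voom in all groups 78). Chow gave 0 with limma in every setting (227 unadjusted, voom 0) but 4 with only the compared groups, and 0 to 0 with each library left out. Between diets the counts ranged from 6981 to 7567 with placebo and from 9048 to 9435 with rosuvastatin with each library left out, and a fold of 1.2 gave 4955 with placebo. The interaction, 1, ranged from 1 to 150. It was 3 with the replicate block, 2 with a pseudocount of 10, 3 with voom, 15 without the libraries highest in Rn45s and, with limma, 0 at 5 RPKM and 0 without those highest in Hba-a1 (1807 unadjusted in full, voom 3). Of 28 same-numbered pairs of libraries 3 correlated above 0.1, so the numbers are no pairs, and the block gave 685 genes on the Western diet.

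Lists called ranged, with each library left out, from 16 to 20 on the Western diet, 1 to 3 on chow, 3 to 6 between diets with placebo, 10 to 14 with rosuvastatin and 12 to 17 for the interaction. With an estimated correlation they were 0, 0, 0, 1 and 0, and with fry 11, 0, 12, 17 and 1. Between diets with placebo, no filter gave 7. With only the compared groups chow gave 4, and with an estimated correlation added the counts were 0 on the Western diet, 0 on chow, 1 between diets with placebo and 0 with rosuvastatin.

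Some directions turned. For rosuvastatin on the Western diet, fitted Apob (-0.04) ranged from -0.26 to 0.080 and Ldlr (0.04) from -0.15 to 0.29 with each library left out, and Ldlr was -0.117 with median-ratio scaling, -0.0731 with upper-quartile scaling, -0.0989 with voom and -0.110 with the length trend removed. Between diets with placebo, Hmgcr (0.19) was -0.264, -0.129, -0.321 and -0.399 in that order. With the length trend removed, Apob (0.89) was -0.0896 with placebo and, from 0.91, -0.230 with rosuvastatin. The interaction's cholesterol synthesis median ranged from -0.15 to 0.52. No list turned elsewhere. Of named genes over all alternatives, 1291 values on the Western diet kept direction and side of the threshold and 229 lost the call, 519 on chow kept both and 4 gained a call, and between diets 1106 and 792 kept both while 5 and 4 lost the call.

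Depth limits genes near the filter, since 1 read of 2 kb is up to 0.236 RPKM.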

Other observations

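The tests in this part were chosen only after the result was seen, except limma's calls in all libraries and in the chow groups alone and the interaction's list test.

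The authors' own columns call 252 genes for rosuvastatin on the Western diet, 143 higher and 109 lower. Of the 227 that were tested here, 187 were called, and 227 had the same direction. On chow the authors' columns call 27 genes, 24 higher and 3 lower. Of the 26 tested here all 26 had the same direction and limma called 0 in all libraries (227 unadjusted, voom 0) and 4 in the chow groups alone (Scd2, Sqle, Mvk and Cyp51), which the authors' columns call too. Across genes, which are not independent replicates, Spearman's rho between the authors' log2 fold changes and those computed here was 0.975 on the Western diet and 0.958 on chow.

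The cholesterol synthesis genes may respond alike to rosuvastatin on both diets. Of the 19 tested members 19 were above the median of all genes on both diets, against 26.7% of all genes, while over all genes the 2 effects hardly correlated (Spearman's rho = 0.099). The interaction test neither called the list nor shows that the effects are equal.

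Arntl and Dbp, clock genes of opposite phase, varied within groups, which may reflect collection at different times of day. Spearman's rho between them was -0.9429 in the 6 libraries of each rosuvastatin group (exact permutation p = 0.0167, adjusted 0.050 over 6 relations, which does not pass). Pearson's r was -0.925 on the Western diet (exact permutation p = 0.0028, adjusted 0.0167) and -0.941 on chow (exact permutation p = 0.0125, adjusted 0.0375). Without the 2 libraries farthest from the median r was -0.754 and -0.954 in that order. The labels give no time of collection.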
